A study of Mus musculus with 2 samples.

How the data were processed

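Single-nucleus RNA sequencing was available for 2 libraries, 1 from 20 pooled cochleae of the group called Serpine2 cOE in the labels and 1 from 19 pooled control cochleae. The mice were at postnatal day 7 and had received tamoxifen at day 1. The genotype label of the first group gives Lgr5-EGFP-CreER together with loxP-flanked Serpine2 on both alleles, and that of the control gives the same Serpine2 alleles without the driver. The series calls the first group conditional overexpression, but a loxP-flanked allele does not by itself say whether recombination raises or removes Serpine2. The construct that follows recombination is not described in the sources used here. It is therefore not known whether its transcripts carry the 3' end that the assay counts for Serpine2, and the Serpine2 values do not separate them from those of the native gene.

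Per the file headers, the deposited values are counts, 1 whole number of UMIs per gene and barcode, written by the authors with Cell Ranger 8.0.1. Per the labels, the authors used the 10x Chromium 3' v3.1 kit and an Illumina NovaSeq instrument, aligned with STAR in a version not given, and filtered barcodes with Cell Ranger. The labels give the genome build as GRCm39 in one place and as mm10 in another. Of the 33696 gene identifiers in the files, 33185 were found in GENCODE release M39, from which gene positions were taken. No value depended on coordinates.

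The Serpine2 cOE library had 12014 barcodes and 40429121 UMIs (median 2338 per barcode), and the control library 9820 barcodes and 31158971 UMIs (median 2168.5). Nuclei were kept with at least 500 genes and a mitochondrial share of at most 5%, which left 10817 and 8953. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 21.5% of cOE and 0% of control nuclei, outside the accepted range of 0.5% to 20%. The rule set for that case removed the top 0.8% of scores per 1000 barcodes, 1040 nuclei in cOE (9.61%) and 703 in control (7.85%). The kept nuclei numbered 9777 and 8250, with medians of 2401 and 2247 UMIs, 1540 and 1451 genes, and mitochondrial shares of 0.394% and 0.300%. At these depths supporting cell-like nuclei summed to 956271 and 615332 UMIs, so a gene with 0 UMIs there could still stand at 3.14 and 4.88 CPM.

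Both libraries were clustered together without integration. Counts were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were chosen with library as batch key, and 50 principal components, 15 neighbours and Leiden resolution 1 gave 26 clusters. Serpine2, Lgr5, Xist, Tsix, Y-linked, mitochondrial, ribosomal protein and haemoglobin genes were left out of clustering. Clusters were named from 16 marker lists. A marker counted when it was in at least 10% of the cluster's nuclei and 2-fold higher than elsewhere. A name needed at least 3 such markers, and more than any other list. Where listed markers were among the 10 leading genes, more had to be its own than of any other list. If another list had any there, 1.5 times as many markers as the next list were needed. With no listed marker among the 10, a name needed at least 6 markers and 1.5 times as many as the next list, or a next list with at most 1. A cluster of low depth with none of its own markers among the 10 stayed unnamed. This rule was made stricter after a cluster of low-depth nuclei at resolution 2 had been named supporting cell. Hair cell-like nuclei were clustered again at resolution 0.5 into 6 sub-clusters, of which 3 carried at least 3 markers of another class and are called mixed. Clusters 4, 20 and 22 formed the supporting cell class. Unnamed clusters were used only in the class of other nuclei, and cluster 24 is given separately because it missed the naming rule.

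For each class, UMIs were summed per library and scaled to the class total as CPM, with exact Poisson 95% intervals. The ratio of cOE over control has an exact conditional 95% interval, and shares of nuclei have Clopper-Pearson intervals. With 1 library per group, no significance test, p-value, standard error or number of changed genes over all genes was computed. Members of a gene list were only counted by whether their own counting interval lay above or below 0. The share of all genes with such an interval is not given, so these counts alone do not set a list apart. A count of 0 was given the limit allowed by 3 counts. Shares of nuclei with a UMI or with several markers were taken after thinning each nucleus to 1000 UMIs, leaving out shallower nuclei, and unthinned. A nucleus counted as proliferating with at least 3 of 14 proliferation markers. Alternative scaling factors came from the TMM method of edgeR 4.0.16 in R 4.3.3 (0.987 and 1.01 for supporting cells, 0.999 and 1.00 for hair cells).

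The rule for named genes was set before the data were examined, as were the marker lists, the 18 gene lists and the alternatives of the next paragraph that are not called added. In supporting cells and in hair cells, genes with at least 50 UMIs over both libraries and at least 20 CPM in 1 of them were ranked by the bound of the ratio interval nearest 0, and the 12 highest and 12 lowest are given. A second ranking by the gap to the other nuclei gives 5 each way. Clone names and sex, mitochondrial, ribosomal protein and haemoglobin genes were left out of both rankings. Serpine2, Lgr5, Atoh1, Pou4f3, Sox2, Myo7a, Slc26a5 and Slc17a8 are always given, and 2 to 4 members may be named for each list. The interferon-related genes and the clusters named outside the hair cell and supporting cell classes were chosen after their values were seen. Each list's median log2 ratio was placed among those of 10000 random lists matched on total UMIs in 20 bins, as a description of these 2 libraries. The listed genes Ddit3, Myo15 and Nrg1 were missing from the files. In the gene lists, intervals of single members are given for some members only. A member needed at least 50 UMIs in the nuclei compared, so a list's median covers fewer genes in smaller sets of nuclei.

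The alternatives tried were no doublet removal, other filters (at least 200 genes with a mitochondrial share up to 10%, or at least 1000 genes), Leiden resolutions of 0.5 and 2, clustering of each library separately, a hair cell call from at least 4 of 31 markers after thinning, TMM factors, thinning, equal weight per nucleus, other UMI minimums (10 and 1), and other marker or Lgr5 thresholds. Added alternatives, chosen after the data were seen, left out mixed sub-clusters, cluster 12 or the top nucleus of each gene, used outer hair cell-like nuclei alone, or added cluster 24. The ratio intervals, ranking and list percentiles were tested on simulated data with known 2-fold differences. There, 96.0% and 95.7% of intervals held the true value in the 2 classes, the 12 top genes were all planted ones, and 4.5% and 5.5% of unchanged lists fell in the outer 5% of percentiles. The simulated sums were independent counts, the model that the intervals assume, so this checked the calculation only. UMIs concentrated in single nuclei and genes that vary together, both possible in the real data, were not simulated.

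Software was Python 3.11.15 with anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Sequence reads, splicing and trajectories were not analysed here.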

Results

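Nuclei from 20 pooled cochleae of the group called Serpine2 cOE in the labels were compared with nuclei from 19 pooled control cochleae, taken at postnatal day 7 after tamoxifen at day 1. Each group was 1 library, so no difference given here has a replicate check. Every interval is a 95% interval of counting error only. The control mice lacked the Lgr5-EGFP-CreER allele, so the driver allele and the state of Serpine2 differed together. Cell classes were named from marker genes, and a class name means a cluster that resembles the named cell type.

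Serpine2 (ENSMUSG00000026249, chromosome 1, 79763323 to 79839144, minus strand in GRCm39) encodes a secreted inhibitor of thrombin and of plasminogen activators. In supporting cell-like nuclei it stood at 243 CPM (interval 212 to 276) in Serpine2 cOE and 179 CPM (147 to 215) in control. The log2 ratio of cOE over control was 0.44 (0.11 to 0.78), from 232 and 110 UMIs. Serpine2 was higher in cOE in each of the 3 supporting cell-like clusters, with log2 ratios of 0.32 (-0.23 to 0.89) in cluster 4, 0.56 (-0.00 to 1.15) in cluster 20 and 0.51 (-0.15 to 1.20) in cluster 22, which held 484 of the 498 Lgr5 UMIs of cOE supporting cell-like nuclei. Hair cell-like nuclei had 56.1 and 57.7 CPM of Serpine2 (log2 ratio -0.04, -0.28 to 0.20). Hair cell-like nuclei outside the mixed sub-clusters (those with at least 3 markers of another class) had 31.4 and 22.7 CPM (0.47, -0.25 to 1.23). Whether any of these counts come from the construct is not known. Over all kept nuclei the 2 libraries were close, at 86.0 and 88.9 CPM (-0.05, -0.13 to 0.03). With every nucleus thinned to 1000 UMIs, which also gives each nucleus equal weight, 34 and 29 Serpine2 UMIs were left in supporting cell-like nuclei. The ratio was then -0.53 (-1.29 to 0.23), an interval that included 0 and overlapped the unthinned one. After thinning, 28 of 168 cOE supporting cell-like nuclei (16.7%) and 22 of 99 control nuclei (22.2%) had a Serpine2 UMI, against 64.3% and 58.6% unthinned.

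**Figure D1:**
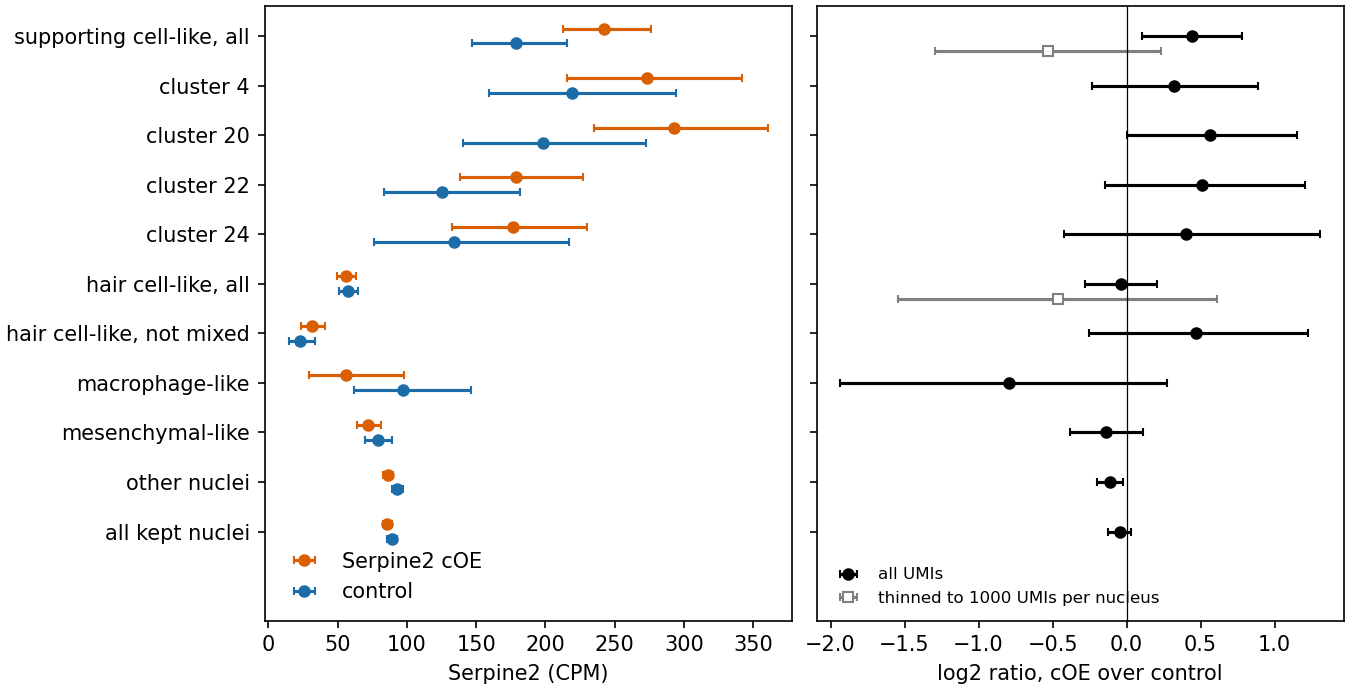
Left, Serpine2 (CPM) by class and cluster in Serpine2 cOE and control, with bars for 95% counting intervals. Right, log2 ratio of cOE over control, with squares after thinning to 1000 UMIs per nucleus: the ratio of 0.44 in supporting cell-like nuclei was -0.53 after thinning.

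Serpine2 was also expressed outside the sensory classes, in some clusters at or above the level of supporting cell-like nuclei. Unnamed cluster 9 had 270 CPM in cOE and 281 CPM in control, and unnamed cluster 25 had 669 and 649 CPM, from 23 and 24 UMIs. Macrophage-like nuclei had 56.2 CPM in cOE and 97.4 CPM in control (log2 ratio -0.79, -1.93 to 0.27). Mesenchymal-like nuclei had 71.9 and 79.1 CPM (-0.14, -0.38 to 0.11). In all nuclei outside the hair and supporting cell classes (the other nuclei), Serpine2 stood at 86.2 and 93.1 CPM (-0.11, -0.20 to -0.02). Clusters among them went both ways, with 0.46 (0.10 to 0.82) in cluster 7, from 182 and 106 UMIs, and -0.79 (-1.38 to -0.21) in cluster 10, so a rise as large as that in supporting cell-like nuclei was also found elsewhere. A Serpine2 UMI was present in 8.32% of 8697 cOE and 8.52% of 6940 control other nuclei after thinning, with 436 and 844 shallower nuclei left out, and in 17.6% and 18.2% unthinned. Median depth was 5027.5 and 4813 UMIs in supporting cell-like nuclei and 2309 and 2177 in the other nuclei.

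Lgr5 (ENSMUSG00000020140, chromosome 10, 115286216 to 115423685, minus strand) encodes an R-spondin receptor and is the locus of the Cre driver. Supporting cell-like nuclei had 521 CPM in cOE and 466 CPM in control (log2 ratio 0.16, -0.05 to 0.37). In control, 1 nucleus held 59 of the 287 UMIs, and without the top nucleus of each library the ratio was 0.33 (0.10 to 0.57). Cluster 22 had 1293 and 1243 CPM (0.06, -0.16 to 0.27). Hair cell-like nuclei had 190 and 174 CPM (0.12, -0.01 to 0.26), and the other nuclei 39.6 and 41.3 CPM (-0.06, -0.19 to 0.07). Clusters among the other nuclei went both ways, with -0.55 (-0.80 to -0.30) in cluster 3, -1.61 (-2.50 to -0.70) in cluster 1 and 0.85 (0.02 to 1.77) in cluster 18. After thinning, 39 of 168 cOE supporting cell-like nuclei had an Lgr5 UMI (23.2%, 17.1 to 30.3) and 23 of 99 control nuclei (23.2%, 15.3 to 32.8). No supporting cell-like nucleus was too shallow to thin. Unthinned, the shares were 38.7% and 39.4%. In macrophage-like nuclei, which should lack Lgr5, the thinned share was 0 of 105 and 0 of 132, which allows up to 2.86% and 2.27%. Those nuclei had median depths of 1534 and 1500.5 UMIs, 12 and 20 of them were left out by thinning, and 1 of 117 and 0 of 152 had an Lgr5 UMI unthinned. When each library was clustered separately, the thinned share of Lgr5-positive supporting cells was 23.9% in cOE and 3.13% in control. The control class was smaller there, at 0.776% of kept nuclei against 1.20% in the main clustering. Its membership thus changed, and these shares do not compare matched nuclei.

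Supporting cell-like nuclei made up 1.72% (1.47 to 1.996) of kept cOE nuclei, 168 of 9777, and 1.20% (0.976 to 1.46) of kept control nuclei, 99 of 8250. The ratio of these shares was 1.43 (1.11 to 1.85). Unnamed cluster 24 carried the supporting cell markers Sox2, Lfng, Hey2, Emid1, Fabp7 and Gjb2 but missed the naming rule. Its share was 0.808% (0.640 to 1.01) in cOE and 0.388% (0.266 to 0.547) in control, 79 and 32 nuclei. With cluster 24 added, supporting cell-like nuclei were 2.53% and 1.59%. Under separate clustering of the libraries the supporting cell share was 1.67% and 0.776%.

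Hair cell-like nuclei were 4.87% (4.45 to 5.31) of kept nuclei in cOE, 476 nuclei, and 4.45% (4.01 to 4.92) in control, 367 nuclei, a ratio of 1.09 (0.953 to 1.26). Of hair and supporting cell-like nuclei together, hair cells were 73.9% (70.3 to 77.3) in cOE and 78.8% (74.8 to 82.4) in control. Of the 6 hair cell sub-clusters, 3 carried at least 3 markers of another class. A further one, number 4, carried the neuron markers Nefm and Rbfox3 and was not counted as mixed. The mixed sub-clusters held 36.6% of cOE and 52.3% of control hair cell-like nuclei, 174 and 192. Nuclei outside them held only 1689329 of 5240043 hair cell-like UMIs in cOE and 1056916 of 4716942 in control. Mixed sub-cluster 1 alone held 2787335 and 2765157. Gene values of hair cell-like nuclei rest on summed UMIs, so most of their counts came from mixed sub-clusters. Without them, hair cell-like nuclei were 3.09% (2.75 to 3.45) in cOE and 2.12% (1.82 to 2.46) in control, a ratio of 1.46 (1.20 to 1.76), and 64.3% and 63.9% of these and supporting cells together. The direction of the hair cell share turned with the filter and the clustering. It was 4.48% and 10.2% with at least 200 genes and a mitochondrial share up to 10%, 5.63% and 7.75% with at least 1000 genes, and 4.93% and 6.91% with separate clustering, where hair cells were 74.7% and 89.9% of hair and supporting cells. Counting each thinned nucleus with at least 4 hair cell markers gave 5.19% and 5.28%.

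**Figure D2:**
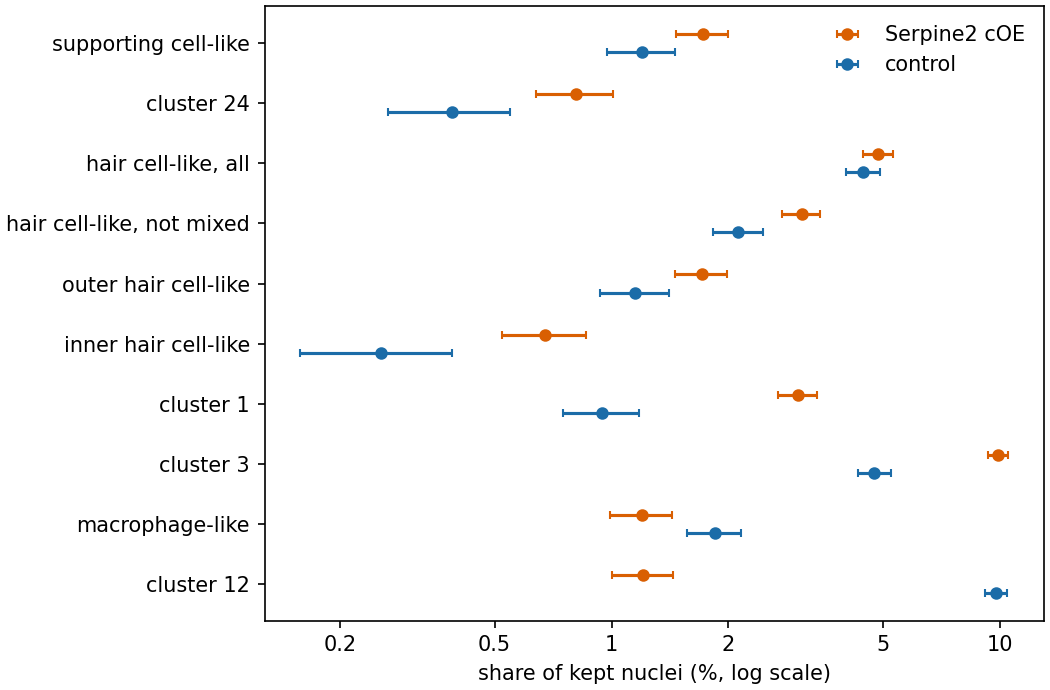
Share of kept nuclei (percent, log scale) by class and cluster in Serpine2 cOE and control, with bars for 95% Clopper-Pearson intervals. Inner hair cell-like nuclei stood at 0.675% and 0.255%, cluster 1 at 3.02% and 0.945%, and cluster 12 at 1.21% and 9.77%.

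Inner hair cell-like nuclei, named from Slc17a8, Fgf8, Otof and Tbx2, were 66 in cOE (0.675%, 0.522 to 0.858) and 21 in control (0.255%, 0.158 to 0.389), a ratio of 2.65 (1.60 to 4.56). Outer hair cell-like nuclei, named from markers that include Slc26a5, Ocm and Ikzf2, were 167 (1.71%, 1.46 to 1.98) and 95 (1.15%, 0.933 to 1.41), a ratio of 1.48 (1.15 to 1.93). Inner hair cells were 28.3% (22.6 to 34.6) of inner and outer hair cell-like nuclei in cOE and 18.1% (11.6 to 26.3) in control. Sub-cluster 4, with Tmc2 among its 10 leading genes, held 69 cOE and 59 control nuclei.

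With at least 3 of 14 proliferation markers after thinning, 0 of 168 cOE and 0 of 99 control supporting cell-like nuclei counted as proliferating, which allows up to 1.79% and 3.03% of nuclei that pass this call. It is not a limit on proliferating cells, since thinning removes markers. Unthinned, 1 cOE and 0 control nuclei counted. Hair cell-like nuclei gave 0 of 476 and 0 of 367 thinned, and 15 (3.15%) and 25 (6.81%) unthinned. Without the mixed sub-clusters, which had the deepest barcodes, 1 and 2 nuclei counted unthinned. Among the other nuclei, 12 of 8697 in cOE (0.138%) and 16 of 6940 in control (0.231%) counted after thinning, and 0.350% and 0.629% unthinned. Macrophage-like nuclei supplied 4 of the thinned nuclei in each library.

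Gdf6, which encodes a BMP family ligand, was higher in cOE supporting cell-like nuclei, at 81.6 against 27.6 CPM (78 and 17 UMIs, log2 ratio 1.56, 0.79 to 2.41), and differed less in the other nuclei (0.25). Cdh2 (N-cadherin) stood at 95.2 and 40.6 CPM (1.23, 0.58 to 1.93; other nuclei 0.02). Strap, which encodes a partner of TGF-beta receptors, was at 45.0 and 14.6 CPM (1.62, 0.56 to 2.84; 0.10 elsewhere). The nuclear receptor gene Rorb was at 899 and 592 CPM (0.60, 0.43 to 0.79), with nearly the same ratio in the other nuclei (0.57). Mia, which encodes a small secreted protein, was higher in supporting cells (0.99, 0.63 to 1.37) and as much higher elsewhere (0.89). Thsd7b was at 280.3 and 156 CPM (0.85, 0.50 to 1.20; other nuclei -0.09). Paqr6 had a log2 ratio of 1.77 (other nuclei 0.83), the small GTPase gene Rab18 1.48 (0.27), the peroxiredoxin gene Prdx5 1.32 (0.23), the interferon lambda receptor gene Ifnlr1 1.29 (0.07) and Zmat3, a p53 target, 1.13 (0.27). Sgcz (1.57) rested on 14 and 8 nuclei, with 25 of its 60 cOE UMIs in 1 nucleus. Ranked by the gap to the other nuclei, Strap came first, followed by Grid2ip (0.63 against -0.87), Ccsap (1.20 against -0.20), Rnf122 (1.14 against -0.23) and Gemin5 (0.89 against -0.45).

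Angpt1, which encodes a ligand of the Tek receptor, was lower in cOE supporting cell-like nuclei, at 8.37 against 71.5 CPM (8 and 44 UMIs in 7 and 20 nuclei). Its log2 ratio was -3.10 (-4.39 to -1.99), -3.13 without the nucleus with most of its UMIs, and -0.11 in the other nuclei. The cadherin genes Cdh4 (54.4 and 164 CPM, -1.59, -2.10 to -1.10) and Cdh6 (49.2 and 138 CPM, -1.49, -2.04 to -0.96) were lower too, with -0.10 and -0.31 in the other nuclei. Agr3, a protein disulfide isomerase gene, was at 88.9 and 244 CPM (-1.45, -1.86 to -1.06; other nuclei 0.22). Supt3 was at 58.6 and 166 CPM (-1.50, other nuclei 0.00), Mybpc1 at 76.3 and 198 CPM (-1.38, -0.23), and Tafa1 at 45.0 and 141 CPM (-1.65, -0.27). Dpp10, which encodes a potassium channel partner, had -1.66 (other nuclei 0.43) and Plpp4 -1.79 (-0.37). Stxbp5l had -1.61 (-0.16), and 0.38 with nuclei of at least 200 genes. Il1rapl2 (17 and 139 UMIs, -3.67) had 116 control UMIs in 1 nucleus, and its ratio was -2.36 without it. Il1rapl2 and Dpp10 were among the 10 leading genes of unnamed cluster 23, with 52 cOE and 35 control nuclei. Other unnamed clusters had Cdh4 (cluster 16), Tafa1 (cluster 15), Stxbp5l (cluster 6) and Ndst3 (cluster 0) among their 10 leading genes. Whether RNA of such clusters in supporting cell-like barcodes differed between the libraries was not tested for these genes. Ndst3 (21 and 61 UMIs, -2.17) was seen in 6 and 3 nuclei, with 39 control UMIs in 1 of them, and its ratio was -1.10 without it. By the gap to the other nuclei, Il1rapl2, Angpt1, Dpp10, Ndst3 and Agr3 stood lowest.

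**Figure D3:**
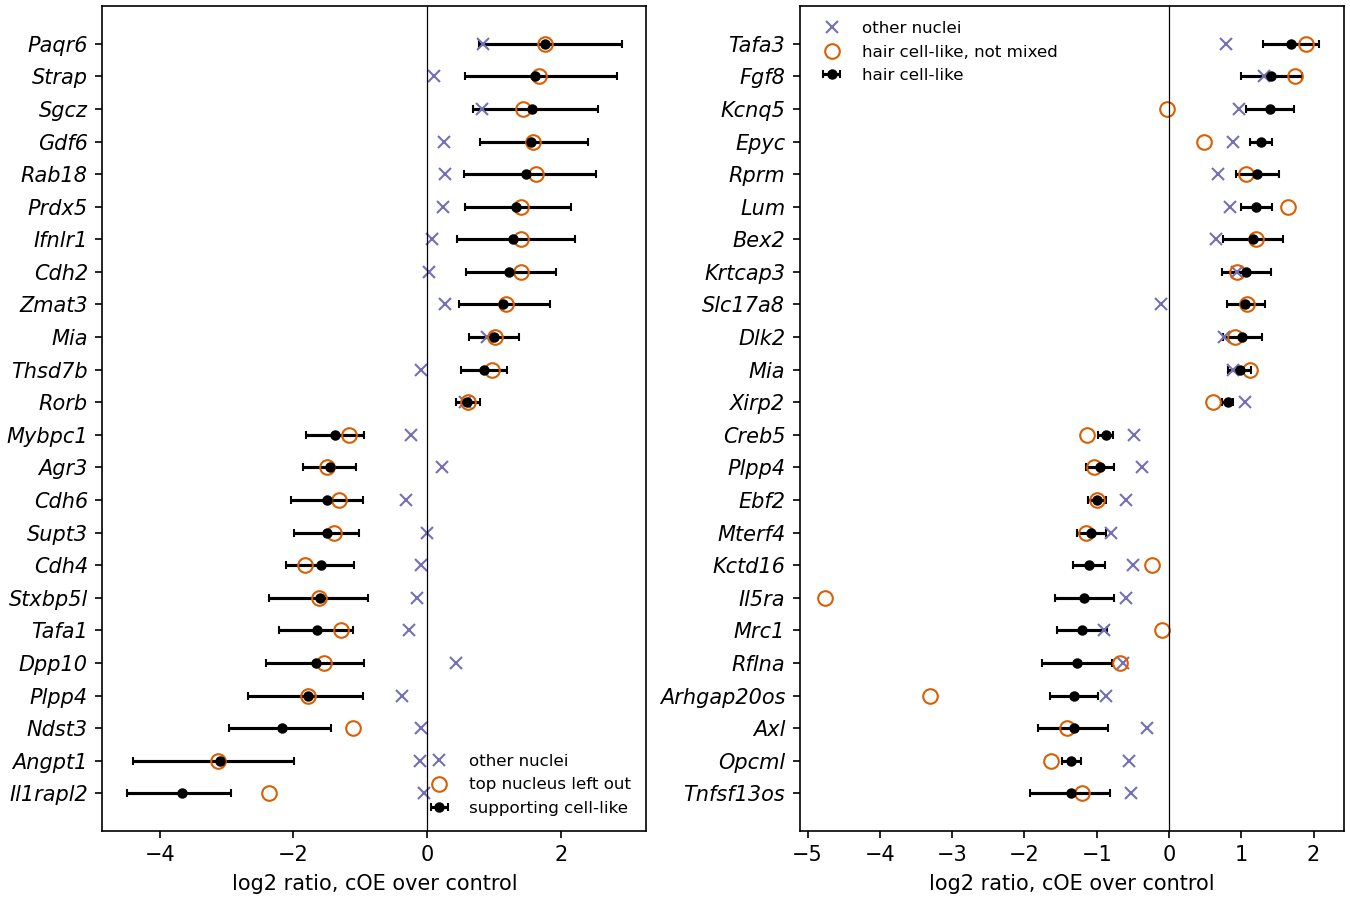
Log2 ratios of Serpine2 cOE over control for the 24 named genes in supporting cell-like (left) and hair cell-like nuclei (right), with bars for 95% counting intervals and crosses for the other nuclei. Circles leave out the top nucleus (left) or the mixed sub-clusters (right): Angpt1 kept -3.13, while Kcnq5 went from 1.39 to -0.02, the latter from few UMIs.

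In supporting cell-like nuclei, 5 hair cell genes had 0 to 4 UMIs in each library. Atoh1, the transcription factor gene that starts hair cell differentiation, had 0, which allows up to 3.14 CPM in cOE and 4.88 CPM in control. Pou4f3 had 4 and 3 UMIs, Myo7a 2 and 1, Slc26a5 1 and 1, and Slc17a8 3 and 3. Sox2, a gene of supporting cells and their progenitors, had 43 and 24 UMIs (log2 ratio 0.21, -0.55 to 0.99). Summed markers of other cell types were not equal between the libraries: in supporting cell-like nuclei, neuron markers had a log2 ratio of -0.89 (-1.18 to -0.59), macrophage markers -1.09 (-1.67 to -0.52), osteoblast or chondrocyte markers -0.56 (-0.79 to -0.33) and erythroid markers 0.72 (0.24 to 1.22).

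Mitochondrially encoded transcripts had the highest list median in supporting cell-like nuclei (0.65, percentile 100 among 10000 matched random lists, 7 of 9 members with an interval above 0), with mt-Cytb at 1.32. Ribosomal protein genes had -0.12 (percentile 0.57), with Rpl8 at -0.44. In TGF-beta and BMP genes the median was -0.16 (percentile 1.32), with Bmp4 at -0.89 (-1.63 to -0.16) and Bmpr2 at -0.43. That median reversed to 0.17 after thinning, 0.02 with each nucleus weighted equally, 0.01 with nuclei of at least 200 genes and 0.04 with separate clustering. Hippo and YAP genes had -0.16 (percentile 4.40; Tead2 -0.84), and extracellular matrix genes -0.06 (11.4), where Col1a2 (-0.86), Tnc (-0.83) and Col2a1 (-0.54) were lower and Col4a3 (0.66) and Otogl (0.36) higher. Notch genes lay near 0 (0.03, percentile 52.2; Hes1 0.67, -0.08 to 1.48), as did Wnt genes (-0.06, 16.7; Fzd6 0.43, Znrf3 0.37) and supporting cell identity genes (0.06, 69.4; Emid1 -0.41, Slc1a3 -0.31).

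FGF and EGF receptor genes in supporting cell-like nuclei had a median of 0.01 (percentile 49.6), with Spred2 at -1.06 (-1.68 to -0.45), Erbb4 at -0.47 (-0.60 to -0.33) and Etv1 at 0.50 (0.03 to 0.99). Apoptosis and p53 genes had -0.05 (32.1), with Bcl2 at 125 and 239 CPM (-0.93, -1.29 to -0.57). Plasminogen and thrombin system genes, the system that Serpine2 acts on, had -0.14 (18.4), with the protease inhibitor genes Timp2 at -0.67 (-1.29 to -0.04) and Timp3 at -0.48 (-0.86 to -0.10). Hair cell transcription factor genes had 0.14 (85.0; Sall1 0.56, Eya1 -0.24), hair bundle genes -0.06 (27.2; Myo6 0.30) and hair cell synapse genes 0.05 (57.7; Cacna1d -0.41). Immediate early genes had -0.01 (46.5; Egr1 -1.05, -1.88 to -0.24). The cyclin-dependent kinase inhibitor genes had 0.15 over 4 members (75.1; Cdkn1b 0.08), and the cell cycle list only 2 measured members, Slbp and Mcm7 (0.22, 75.7). None of the 14 proliferation markers reached the minimum of UMIs there.

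Fgf8, Slc17a8 and Tafa3 were higher in cOE hair cell-like nuclei, where inner hair cell-like nuclei were also more frequent. Fgf8 stood at 36.6 and 13.8 CPM (192 and 65 UMIs, log2 ratio 1.41, 1.00 to 1.84), and Slc17a8, the vesicular glutamate transporter gene of inner hair cells, at 76.7 and 36.9 CPM (1.06, 0.80 to 1.32). Fgf8 had a similar ratio in the other nuclei (1.31), so its rise was not particular to hair cell-like nuclei. Tafa3, among the 10 leading genes of the inner hair cell-like sub-cluster, was at 50.4 and 15.7 CPM (1.68, 1.31 to 2.07). Inside inner hair cell-like nuclei these genes were higher as well, with Fgf8 at 1.02 (0.39 to 1.70), Slc17a8 at 0.63 (0.21 to 1.07) and Tafa3 at 1.21 (0.63 to 1.84). Tmc1 (0.25, 0.04 to 0.47) and the outer hair cell marker Ocm (1.81, 0.11 to 4.17, from 28 and 3 UMIs) were higher there too. Slc26a5, Tmc2, Lgr5 and Serpine2 had intervals that included 0. The rise was thus not limited to genes of inner hair cells. In the same nuclei the 12 lowest genes of hair cell-like nuclei summed to -2.14. Whether RNA of other cells lowered the control values there was not tested. Inside outer hair cell-like nuclei the ratio of Slc17a8 was -0.31. Xirp2, which encodes an actin-binding protein of stereocilia, was at 815 and 463 CPM (0.81, 0.74 to 0.89), and at 0.60 without the mixed sub-clusters. Its ratio was 0.31 (0.15 to 0.46) in inner and 3.69 (2.68 to 4.92) in outer hair cell-like nuclei, the latter from 174 and 8 UMIs. The tumour suppressor gene Rprm had 1.22, Dlk2 1.01, Bex2 1.16 (-0.17 after thinning) and Krtcap3 1.07. The proteoglycan genes Epyc (1.27, other nuclei 0.89) and Lum (1.21, 0.85), and Mia (0.98, 0.89), were higher in both. Epyc, a marker of another class in 2 of the mixed sub-clusters, had 0.48 (-0.00 to 0.97) without them. Lum and Mia were among the 10 leading genes of cluster 10, which held 3.62% of cOE and 2.46% of control nuclei. The potassium channel gene Kcnq5 had 1.39, but -0.02 from few UMIs without the mixed sub-clusters, which leaves its ratio there uncertain. Kcnq5 led cluster 16, which held 2.54% of cOE and 1.32% of control nuclei.

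Opcml, which encodes a neural cell adhesion protein, was lower in cOE hair cell-like nuclei, at 132 against 336 CPM (692 and 1587 UMIs, log2 ratio -1.35, -1.48 to -1.22; other nuclei -0.55; without mixed sub-clusters -1.63). Opcml and Kctd16 (-1.11, and -0.24 without mixed sub-clusters), which encodes a partner of GABA-B receptors, were among the 10 leading genes of cluster 5, a cluster of 9.91% of cOE and 13.5% of control nuclei. The transcription factor genes Creb5 (230.3 and 422 CPM, -0.87, -0.98 to -0.77) and Ebf2 (143 and 285 CPM, -0.996, -1.13 to -0.87) were lower, with -0.49 and -0.60 in the other nuclei. In outer hair cell-like nuclei Opcml stood at -0.05, Creb5 at -0.23 and Ebf2 at 0.09, each from few UMIs (13 and 8, 23 and 16, 9 and 5). The long non-coding RNA Arhgap20os had -1.32 (-3.30 without mixed sub-clusters, 6 and 37 UMIs) and Tnfsf13os -1.36. The mitochondrial factor gene Mterf4 had -1.07, Rflna -1.27, Il5ra -1.17 and Plpp4 -0.95. Of 2 genes of macrophages, Mrc1 (mannose receptor, 20.6 and 47.3 CPM) had -1.20, and -0.09 without mixed sub-clusters from 3 and 2 UMIs, and the receptor kinase gene Axl had -1.32. Summed macrophage markers in hair cell-like nuclei stood at 116 and 167 CPM (-0.53, -0.69 to -0.38), endothelial markers at -0.40 (-0.53 to -0.27) and erythroid markers at 0.64 (0.49 to 0.79).

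Hair cell transcription factor genes were higher in cOE hair cell-like nuclei as a list (median 0.15, percentile 98.1, 9 of 18 members above 0 by their interval and 0 below). Without the mixed sub-clusters the median was 0.12 (percentile 88.3, 2 of 15 above and 2 below), and in outer hair cell-like nuclei 0.08 (79.955). Pou4f3, needed for hair cell survival, was at 35.7 and 22.9 CPM (0.64, 0.29 to 1.00; without mixed sub-clusters 0.45, -0.05 to 0.96), Lhx3 had 0.68, Gfi1 0.60 and Isl1 0.54. Atoh1 had 37 and 20 UMIs (0.74, -0.09 to 1.60; without mixed sub-clusters -0.21, -1.32 to 0.94), and Sox2 36 and 27 (0.26, -0.50 to 1.04). Myo7a, a stereocilia motor gene, was at 41.6 and 36.0 CPM (0.21, -0.09 to 0.51), and Slc26a5, the prestin gene of outer hair cells, at 182.2 and 182.5 CPM (-0.00, -0.14 to 0.13). Hair bundle genes had a median of 0.16 (percentile 99.96), 0.06 without mixed sub-clusters (76.2) and -0.04 in outer hair cell-like nuclei, with Tmc2 at 0.48 and Grxcr1 at 0.47. Synapse genes had 0.24 (99.99) and 0.16 without mixed sub-clusters (98.8), and 0.02 in outer hair cell-like nuclei (70.4), with Cabp2 at 0.95, Pvalb at 0.78 and Otof at 0.36. Summed hair cell markers were themselves higher in cOE (0.26, and 0.14 without mixed sub-clusters).

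Wnt genes had a negative median in hair cell-like nuclei (-0.18, percentile 0.04, 9 of 29 members below 0 by their interval and 3 above), with Rspo3 at -1.85, Nkd1 at -0.60, Rnf43 at -0.53 and Lef1 at -0.47 among the lower ones. Without the mixed sub-clusters their median was -0.12 (percentile 9.12, over 17 of the 29 members). Extracellular matrix genes had -0.16 (0.03, 13 of 37 below and 6 above), with Fn1 (fibronectin) at 74.2 and 125 CPM (-0.75, -0.94 to -0.57). Their median was -0.19 (1.17, 19 members) without mixed sub-clusters, but 0.25 (96.0, 12 members) in outer hair cell-like nuclei alone. FGF and EGF receptor genes had -0.17 (0.595, 7 of 19 below and 4 above), with Fgfr4 at -0.55. Immediate early genes had -0.12 (10.1), with Egr1 at -1.08 (-1.48 to -0.68), Fosb at -1.18 and Fos at -0.91, against Btg2 at 0.46. Over fewer measured members their median was 0.22 without mixed sub-clusters (91.5, 6 of 14 members) and 0.52 in outer hair cell-like nuclei (99.1, 4 members). Supporting cell identity genes had 0.22 (99.7; Fabp7 0.79, Gjb2 0.71), reversed to -0.10 after thinning and -0.05 with each nucleus weighted equally. Mitochondrially encoded genes had 0.42 (100), beside a median mitochondrial share of 0.202% in cOE and 0.154% in control.

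Notch genes in hair cell-like nuclei had a median of 0.10 (percentile 88.8), with Hey1 at 0.93 and Hey2, a supporting cell marker in 2 of the mixed sub-clusters, at 0.73 against Notch2 at -0.42. Without the mixed sub-clusters that median was -0.07 over 8 of the 18 members (20.2, 0 members above 0 by their interval and 2 below). TGF-beta and BMP genes had 0.07 (87.7; Fst 0.78, Smad3 -0.56), and -0.12 without mixed sub-clusters, and Hippo and YAP genes -0.03 (23.0; Tead2 -0.46). Cell cycle genes had 0.03 (61.6; Mki67 0.43, Ccnd2 -0.68), proliferation markers -0.11 (31.9), cyclin-dependent kinase inhibitors -0.09 (19.9; Cdkn2d 0.36) and apoptosis genes 0.01 (50.8; Gadd45g 0.82). Without mixed sub-clusters these became 0.41 (5 of 14 members), 0.58 (1 gene), 0.12 (5 of 7) and -0.04 (7 of 16). Plasminogen and thrombin system genes had 0.05 (72.0), and -0.13 without mixed sub-clusters, with Lrp1, the receptor that takes up Serpine2 complexes, at -0.78 (-1.01 to -0.55). Ribosomal protein genes had 0.01 (31.2; Rps6 -0.37).

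**Figure D4:**
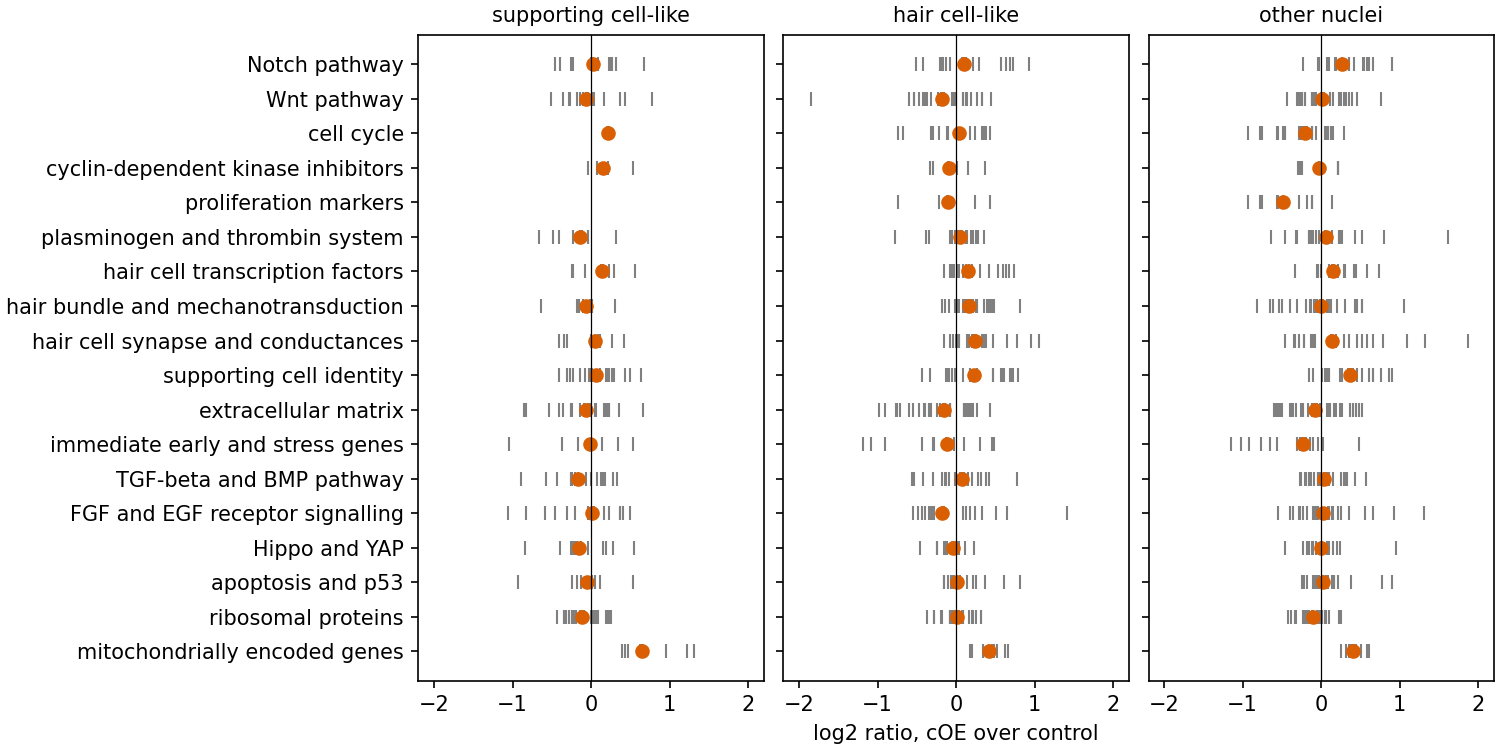
Log2 ratios of Serpine2 cOE over control for the members (ticks) and the median (circles) of 18 gene lists in 3 classes of nuclei. Mitochondrially encoded genes had medians of 0.65, 0.42 and 0.41 from left to right, and supporting cell identity genes 0.06, 0.22 and 0.37.

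Supporting cell identity genes were higher in cOE among the other nuclei (median 0.37, percentile 100), with Cryab at 0.91 (0.80 to 1.02), the connexin gene Gjb6 at 0.87 and Sox2 at 0.77. Notch genes were higher there as well (0.27, percentile 100, 12 of 19 members above 0 by their interval), with Hey1 at 0.91, Lfng at 0.66 and Hey2 at 0.61 against Rbpj at -0.23. Intervals clear of 0 were common in these nuclei: of 38 extracellular matrix genes, 12 lay above 0 and 20 below. The other nuclei pool many clusters, so ratios in them mix cluster sizes with expression, and the 2 were not separated. This also holds where such ratios are given beside named genes. Several unnamed clusters were larger in cOE. Cluster 24, which carried the markers Sox2, Lfng and Hey2, was 0.808% of cOE and 0.388% of control nuclei (2.08, 1.37 to 3.25). Cluster 1, with the glial markers Mbp, Sox10, Erbb3 and Mal and with Otoa among its 10 leading genes, was 3.02% (2.69 to 3.38) of cOE and 0.945% (0.748 to 1.18) of control nuclei, a ratio of 3.19 (2.48 to 4.15). Cluster 3, with the greater epithelial ridge markers Otogl, Otog, Tecta and Otoa and with the lateral epithelium marker Ano1 among its 10 leading genes, was 9.91% and 4.75% (2.09, 1.85 to 2.35). Unnamed cluster 17, with 4 markers each of Reissner membrane and of marginal cells, was 6.05% and 4.17% (1.45, 1.27 to 1.66). Macrophage-like nuclei were 1.20% and 1.84% (0.650, 0.506 to 0.832), mesenchymal-like nuclei 15.6% and 17.1% (0.909, 0.845 to 0.978), and neuron-like cluster 18 held 57 and 33 nuclei (1.46, 0.933 to 2.31). At resolution 2, neuron-like nuclei were 48 and 10 (4.05, 2.02 to 8.98). Cluster 12, led by Actb and including Tpt1 and Tmc1, with a median of 892 UMIs, was 1.21% of cOE and 9.77% (9.14 to 10.4) of control nuclei (0.124, 0.101 to 0.15), and was thus mostly a cluster of 1 library.

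Proliferation markers were lower in cOE among the other nuclei (median -0.49, percentile 0.06, 5 of 11 members below 0 by their interval and 0 above), with Top2a at 103 and 142 UMIs (-0.76, -1.14 to -0.38) and Prc1 at -0.56, and cell cycle genes had -0.20 (0.94). At the finer resolution of 2.0, a cluster led by Top2a held 9 cOE and 20 control nuclei. Immediate early genes were lower too (-0.23, percentile 0.01, 9 of 20 below and 0 above), with Egr1 at 34.5 and 65.4 CPM (-0.92, -1.04 to -0.80), Fosb at -1.15 and Fos at -1.02. All 11 mitochondrially encoded genes were higher (0.41, 100), beside a median mitochondrial share of 0.408% in cOE and 0.311% in control. Extracellular matrix genes had -0.08 (0.54; Col1a1 -0.60), and ribosomal protein genes -0.10 (0.52; Rpl4 -0.43). Hair cell transcription factor genes had 0.16 (98.5; Isl1 0.74), synapse genes 0.14 (98.6; Pvalb 1.32) and bundle genes 0.00 (48.1; Tmc1 -0.66).

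Wnt genes in the other nuclei had a median of 0.01 (percentile 40.4; Rspo2 0.77, Notum 0.45). Plasminogen and thrombin system genes had 0.06 (77.2), with Serpini1, a relative of Serpine2, at 150 and 40 UMIs (1.61, 1.10 to 2.15) and Lrp1 at -0.46. TGF-beta and BMP genes had 0.04 (59.2; Id4 0.57), FGF and EGF receptor genes 0.02 (55.0; Fgf8 1.31, Fgf10 0.93), Hippo and YAP genes -0.00 (37.1; Ccn2 0.95), apoptosis genes 0.02 (53.8; Gadd45g 0.91) and cyclin-dependent kinase inhibitors -0.03 (26.6; Cdkn1b 0.22).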

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

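The alternatives for clusters, sub-clusters and top nuclei named below as added were chosen only after the result was seen, and the others were planned. Supporting cell-like nuclei were few (168 and 99), each group was 1 pooled library, and the control lacked the driver allele. No paired analysis was possible because each group had 1 library. For the main results, 40 alternative values stayed within the set tolerance, 33 moved and 1 reversed. A value counted as reversed only if its sign changed and the main difference was clear of counting error (or, for a list, of the random lists). Other changes of sign, such as those of the hair cell share below, counted as moved or stayed. Among the remaining gene and list results, 689 values stayed, 209 moved and 14 reversed. Values below are cOE minus control in percentage points for shares and log2 ratios for genes, and the cause was not tested.

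Supporting cell and hair cell shares moved as follows. The hair cell share of kept nuclei differed by 0.420, by 0.817 with doublets kept, -5.77 with at least 200 genes and a mitochondrial share up to 10%, -2.12 with at least 1000 genes, -1.98 with separate clustering and -0.0873 with at least 4 markers after thinning. It differed by 0.973 with mixed sub-clusters left out (added) and -0.00210 with cluster 12 left out (added). Hair cells as a share of hair plus supporting cells differed by -4.84, by -1.03 at resolution 0.5, -15.3 with at least 200 genes, -9.19 with at least 1000 genes, -15.2 with separate clustering, 0.387 without mixed sub-clusters (added) and -7.86 with cluster 24 (added). The supporting cell share differed by 0.518, by 0.306 at resolution 0.5, 0.415 with at least 200 genes, 0.410 with at least 1000 genes, 0.891 with separate clustering and 0.939 with cluster 24 (added). The proliferating share of supporting cells stayed at 0 or within tolerance in each alternative run.

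Lgr5-positive supporting cells differed by -0.0180, by -0.704 unthinned, 1.84 with at least 2 UMIs and 20.8 with separate clustering, where classes were named within each library. The supporting cell class was then 1.67% of cOE and 0.776% of control nuclei, so differences under separate clustering may reflect which nuclei were named. Serpine2 in supporting cells had 0.44, which reversed to -0.53 after thinning, and was 0.17 with each nucleus weighted equally and 0.13 with separate clustering. The median over all measured genes in supporting cells was 0.0160, and 0.0533 with TMM factors, 0.0276 thinned, 0.0373 with separate clustering, 0.00138 with at least 10 UMIs, -0.00802 with at least 1 UMI and 0.0531 without each gene's top nucleus (added). In hair cells it was 0.0112, and -0.0112 with equal weights, -0.00600 with at least 200 genes, -0.00620 with separate clustering, 0.0180 in outer hair cell-like nuclei (added), -0.00148 with at least 10 UMIs and -0.0219 with at least 1 UMI.

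Further gene and list results that passed the set rule in the main analysis and changed sign were these. In supporting cells, Stxbp5l went to 0.38 with at least 200 genes, and the TGF-beta and BMP list to 0.17 thinned, 0.021 with equal weights, 0.0080 with at least 200 genes and 0.037 with separate clustering. In hair cells, Kcnq5 went to -0.025 without mixed sub-clusters and -0.75 in outer hair cell-like nuclei (both added, from few UMIs). In outer hair cell-like nuclei (added), Slc17a8 went to -0.31, Ebf2 to 0.094, the hair bundle list to -0.040 and the extracellular matrix list to 0.25. Bex2 went to -0.17 thinned, and the supporting cell identity list to -0.10 thinned and -0.046 with equal weights. Values that had not passed that rule changed sign in hair cells without mixed sub-clusters (added) too: the immediate early list went to 0.22, Notch to -0.07, TGF-beta and BMP to -0.12, plasminogen and thrombin to -0.13, kinase inhibitors to 0.12, apoptosis to -0.04, proliferation to 0.58 from 1 gene, Serpine2 to 0.47, Atoh1 to -0.21 and Lgr5 to -0.15. These list medians cover fewer genes there. Measured members were 6 against 14 for immediate early, 8 against 18 for Notch, 10 against 17 for plasminogen and thrombin, and 7 against 16 for apoptosis. A list's change of sign can thus come from the members left out.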

Other observations

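The tests of cluster 12 and of cluster 1 were chosen only after the result was seen. Those of the 12 genes lower in hair cells were written before, except the one on the share of mixed sub-clusters, but the mixed-barcode test was given added requirements, on the interval of the summed ratio and on inner and outer hair cell-like nuclei each, after its value was seen. In the test on inner and outer hair cells, the thresholds were rewritten after its value was seen.

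Several interferon-related genes, chosen after their values were seen and not tested as a list, were lower in cOE among the other nuclei. The immunity-related GTPase gene Iigp1 was at 76.4 and 112 CPM (log2 ratio -0.55, -0.64 to -0.47), Irgm2 at 11.4 and 21.2 CPM (-0.89, -1.11 to -0.68), and Nlrc5, an activator of MHC class I genes, at 4.17 and 8.99 CPM (-1.11, -1.46 to -0.76). Psmb8 (-0.46), Psmb9 (-0.47) and B2m (-0.24) were lower too. Isg15 (0.32, -0.37 to 1.04) and Ifit3 (0.29, -0.22 to 0.82), type I response genes, and Gbp2 (-0.32, -0.85 to 0.22) and Tgtp2 (-0.10, -0.58 to 0.39) had intervals that included 0. In hair cell-like nuclei Nlrc5 stood at -2.51 from 9 and 46 UMIs and Irgm2 at -1.52. In supporting cell-like nuclei Irgm2 stood at -3.03 from 4 and 21 UMIs. Macrophage-like nuclei had Iigp1 at 1.15 (0.21 to 2.15). At resolution 2, a cluster led by Iigp1 held 70 cOE and 169 control nuclei (0.716% and 2.05%).

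The 12 genes lower in cOE hair cell-like nuclei, among them Opcml, Creb5 and Ebf2, had a median log2 ratio of -1.18, against -0.57 in the other nuclei. Within sub-clusters, the 12 genes summed were lower in all 6, the highest at -0.48 (-0.75 to -0.21). The mixed sub-cluster with most UMIs had -0.98 (-1.04 to -0.92), from 3177 and 6229 UMIs. The gap was thus not only one of a larger share of mixed sub-clusters among control hair cells. This argument is weakened because the genes were chosen as lowest in these same nuclei, which partly builds in lower sums within the parts. It does not address the amount of other RNA within a sub-cluster. RNA of other cell types within barcodes stays open: outside the mixed sub-clusters the median was -1.14, past the bound of -0.8 set before, but that bound was wrong because it took this pool to be free of such barcodes. Sub-cluster 4 carried the neuron markers Nefm and Rbfox3, and outer hair cell-like nuclei had only -0.56 (-1.04 to -0.07). In inner hair cell-like nuclei the sum was -2.14. There, 5 of 21 control nuclei held 119 of 155 UMIs, at a median depth of 12151 against 6506. In cOE, 5 of 66 nuclei held 52 of 94 UMIs, and the ratio without these nuclei was not computed. A lower level of these transcripts in free RNA could not be decided in macrophage-like nuclei, where the sum without Mrc1 and Axl had -0.026 (-0.41 to 0.36) from 110 and 124 UMIs, and an effect of the genotype on hair cells was not tested.

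Cluster 12, led by Actb, was 9.77% of control and 1.21% of cOE nuclei. Low depth alone is argued against, since of kept nuclei under 1000 UMIs (4.46% of cOE and 10.2% of control) 13.5% in cOE and 60.1% in control fell in it, a ratio of 4.44. That most of the cluster was hair cells of low depth is argued against as well, unless free RNA diluted them. Hair cell markers, Tmc1 included, stood at 0.145 of their level in control hair cell-like nuclei outside the mixed sub-clusters. A minority of hair cell nuclei in the cluster is not excluded by this average. The hair cell share of control nuclei was 4.45% in the main setting. It was 10.2% with at least 200 genes and a mitochondrial share up to 10%, and 6.91% with separate clustering. With at least 1000 genes, a filter against low depth, it was 7.75%. Whether the added hair cells came from cluster 12 is not given here. A difference in nuclei preparation or free RNA between the 2 libraries may underlie the difference in cluster 12 and was not tested.

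Cluster 1, which carried Otoa and glial markers, was more frequent in cOE by 3.19 (2.48 to 4.15). A larger yield of cells that express Lgr5 at day 7 stays open for cluster 1, where Lgr5 was at 29.4 CPM in cOE and 89.7 CPM in control. The share ratio of the Lgr5-rich cluster 22, 1.53 (0.987 to 2.42), lay below that of cluster 1, but with close bounds. Other clusters with more Lgr5 than cluster 1 in both libraries rose unequally. Their share ratios were 2.09 (1.85 to 2.35) in cluster 3, 1.92 (1.53 to 2.43) in cluster 16 and 2.08 (1.37 to 3.25) in cluster 24. Cluster 14 had 1.20 (0.921 to 1.58) and hair cell-like nuclei 1.09 (0.953 to 1.26). For inner hair cell-like nuclei (2.65, 1.60 to 4.56) the interval overlapped that of cluster 22, and cells that expressed Lgr5 only earlier could not be traced. More medial tissue taken along at dissection stays open: the ratio of inner to outer hair cell-like nuclei was 1.79 times that of control (1.00 to 3.27), but the inner share of both was 1.56 times (0.945 to 2.69). A biological growth of cluster 1 stays open as an untested hypothesis.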
